A study of Mus musculus with 6 samples.

How the data were processed

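RNA-seq was analysed for 4 libraries of Lgr5-positive hair follicle stem cells (HFSC) from C57BL/6 mice, 2 with the genotype Ring1a/b-/- (knockout) and 2 wild type. Ring1b ChIP-seq, which sequences the DNA bound by an antibody's target, was analysed as 1 peak list from wild-type HFSC and 1 from wild-type intestinal stem cells (ISC). Per the labels, each RNA sample was made from 3000 sorted cells with SMART-seq2, a full-length method that copies polyadenylated RNA and amplifies it by PCR. Each ChIP used sorted Lgr5-GFP cells and an antibody made in the authors' laboratory. The ChIP cells of the skin came from follicles synchronised in the growth phase, per the labels' protocols.

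The submitters' processing notes name bcl2fastq 2, TopHat2 2.1.1, Bowtie 1.2.2, Picard 1.62, HTSeq 0.7.2, MACS2 2.1.1 and DESeq2, with build mm9. The version given for DESeq2 there, 3.7, is not a DESeq2 release number. The role, order and settings of these tools, the gene annotation, the use of strand, any removal of duplicate reads and the control used for peak calling are not given in the sources used here. The count table that the authors deposited holds whole-number counts for 23377 gene symbols with no normalization, a column per library. The normalized table deposited by the authors holds a signal, the same counts divided by 1 constant per library; DESeq2 size factors computed from the counts (1.20 and 1.92 for the knockout, 0.63 and 0.72 for the wild-type libraries) gave the same values. The comparison table of the authors gives, per the file headers, mean normalized signal, log2 fold change of knockout over wild type with its standard error, a Wald score, and p-values before and after adjustment. Its marks of higher and lower genes were read from the file: every marked gene had a log2 fold change of at least 1 in size, and the highest adjusted p among them was 0.0998. The deposited peak lists give for each peak a score, a fold over the caller's background, and the −log10 of its p and q. These peak values are the authors' own and were used only to describe, rank or filter peaks within a list.

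Counts were tested in R 4.3.3 with edgeR 4.0.16: filterByExpr at its defaults, which left 13134 genes, TMM factors, and a quasi-likelihood test (robust glmQLFit, glmQLFTest) with genotype as the only term. Genes with a Benjamini-Hochberg adjusted p under 0.05 were counted as higher or lower. The 26 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, adjusted over the lists, and members were also adjusted over their list alone. Lists with fewer than 3 tested members would have had no set test. The lists were PRC1 subunits, PRC2 subunits, Hox genes, other developmental transcription factors, cell cycle inhibitors, hair follicle stem cell, basal keratinocyte, epidermal differentiation, stress keratinocyte, hair lineage, sebocyte, Merkel cell, melanocyte, fibroblast and dermal papilla, leukocyte, endothelial and mural, Schwann and nerve, intestinal epithelium, Wnt response, Hedgehog response, BMP and TGF-beta, S phase, mitosis, p53 target, dissociation response, and adhesion and EMT genes. Expression is given as CPM, counts scaled to a common depth on TMM-scaled library sizes. Standard errors (SE) were derived from the test, as the size of the fitted log2 fold change over the square root of its F statistic.

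The genes named were set by a rule: both targeted genes, then genes past the threshold with a log2 fold change of at least 1 in size, no overlap between groups and at least 5 CPM in both libraries of the higher group, up to 12 per direction by size of change plus 5 per direction by p. Symbols of predicted or unnamed transcripts were passed over. From each list the rule took up to 4 members past the threshold over all genes tested, or the 2 members of highest mean CPM where there were none. Members past the threshold over their list alone, or named as further markers, were chosen after their values were seen. Some genes that the rule names are not reported here. The gene lists, this rule, the tests and most alternatives were fixed before the data were examined.

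Where every library of a group had 0 counts, a fold was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts in a group, the ratio is given with a 95% counting interval. Intervals and floors cover counting error only, since PCR copies are not independent molecules. Total counts ran from 2785843 to 7740945 per library, and the knockout libraries were the deeper pair.

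Peaks were compared in Python 3.11.15 by an overlap of at least 1 bp, with Wilson 95% intervals for shares and 1000 random placements within the span of each chromosome. Positions are 1-based on mm9. Tables with GRCm38.p6 gene names and lengths served for gene length only (99.5% of the abundant genes had a value), and none of their coordinates were used. An mm9 gene annotation was not used here, so peaks carry no gene names and the planned comparison of promoter peaks with expression was not run.

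Alternatives were median-of-ratios (RLE) factors, library size alone, other low-count filters, DESeq2 1.42.0, limma-voom, a stricter threshold, the replicate number as a block, each library left out, camera with an estimated correlation, fry (a rotation test of whether a list's genes move 1 way on balance), and other peak thresholds and overlaps. Thinning of all libraries to 2785843 counts, removal of a loess trend (span 0.3) on gene length and abundance, and a crossed block were added after the data were seen. The tests of genes were tried on simulated data at these depths with 13134 genes, those of lists with 12726 genes, the removal of the trend with 12703 genes and the overlap of peaks with 400 peaks. Among the 13134 simulated genes edgeR recovered 24, 64, 72 and 88% of 50 genes each changed 2-, 4-, 8- and 16-fold, with 4 false calls among 12934 unchanged genes. The changed genes were drawn from those with a mean above 5 CPM, so recovery at lower counts was not tried. DESeq2 recovered 32, 68, 80 and 96% with 32 false calls, and limma-voom 8, 40, 50 and 68% with 0. In the 12726 genes with a list of 33 raised members, camera gave an adjusted p of 1.69e-18, camera with an estimated correlation 0.64 and fry 0.196, so the last pair missed a list that was changed by construction. Simulated genes were drawn independently of each other, so the preset was not tried on members that move together. In the data, estimated correlations were 0.55 for Merkel cell, 0.5 for leukocyte, 0.3 for S phase and 0.23 for hair lineage genes. For the other lists that camera called they were 0.017 or lower. Of 170 planted peak overlaps 170 were found.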

Results

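Expression was measured by RNA-seq in Lgr5-positive hair follicle stem cells, the cells at the base of the follicle that renew the hair, of the genotypes Ring1a/b-/- and wild type per the labels. Ring1a and Ring1b are the alternative catalytic subunits of Polycomb repressive complex 1 (PRC1), which places ubiquitin on histone H2A and holds developmental genes silent. There were 2 knockout libraries, with 4844381 and 7740945 counts, and 2 wild-type libraries, with 2785843 and 3056593. A count was found for 16130 and 17165 genes in the knockout and 14315 and 15186 in the wild-type libraries. Replicates correlated across genes at Pearson 0.866 (knockout) and 0.887 (wild type) on log2(CPM + 1), against 0.807 to 0.845 between genotypes, where genes are not independent replicates. Counts of same-genotype libraries differed far beyond sampling noise, with a chi-square per degree of freedom of 25 in the knockout and 15 in the wild type; PCR copies are not independent molecules, so this does not show separate preparations. The labels do not say whether the RNA libraries came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Unless stated otherwise, values are CPM as mean ± SD with n = 2 libraries per genotype.

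The targeted genes came first. Ring1, which encodes Ring1a, stood at 15.5 and 18.4 CPM in the knockout and 31.9 and 29.4 CPM in the wild-type libraries, a log2 fold change of -0.85 ± 0.6 (SE) that did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.551). Rnf2, which encodes Ring1b, stood at 151 and 153 CPM in the knockout and 144 and 87.8 CPM in the wild-type libraries, with a log2 fold change of 0.39 ± 0.27 and an edgeR adjusted p of 0.532. These are counts over whole genes and the deleted exons are not given in the sources used here, so neither gene checks the genotype labels.

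The comparison of knockout with wild-type cells asks which genes differ between hair follicle stem cells labelled Ring1a/b-/- and wild type, where PRC1 activity was not measured. Igf2, an imprinted fetal growth factor, rose 46.1-fold from 3.5 ± 1.19 to 164 ± 32.7 CPM, a log2 fold change of 5.53 ± 0.39 (SE; edgeR adjusted p = 0.00467). Igf2bp1, a fetal RNA-binding protein that binds Igf2 transcripts, rose from 0.334 ± 0.472 to 71.6 ± 10.2 CPM, a ratio of 206 with a counting interval of 57 to 1707. Hoxd11, a homeobox gene of posterior and limb patterning, rose from 0 counts to 67.9 ± 13.7 CPM, at least 132-fold higher. Trank1 rose from 0.167 ± 0.236 to 68.5 ± 23 CPM, a ratio of 364 with a counting interval of 65.2 to 14402, and Runx1, a transcription factor of follicle stem cell activation, rose 5.48-fold from 48.5 ± 19.2 to 267 ± 17.8 CPM. Thbs2, which encodes the matrix protein thrombospondin 2, fell 152-fold from 49.6 ± 2 to 0.288 ± 0.121 CPM. Its knockout libraries held 1 and 3 counts, so the size of this fold is uncertain. Each of Hoxd11, Trank1, Igf2bp1, Runx1 and Thbs2 had an adjusted p of 0.0431 in edgeR's test.

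The other genes that rose were F13a1 and Ctss, both known from macrophages and related antigen-presenting cells. F13a1, the catalytic subunit of coagulation factor XIII, rose 20.1-fold from 4.38 ± 1.36 to 89.3 ± 34.2 CPM, and Ctss, the lysosomal protease cathepsin S, rose 14.1-fold from 7.4 ± 1.33 to 105 ± 44.8 CPM (edgeR adjusted p = 0.0444 for each). Both moved with the leukocyte markers, whose summed level was 1009 and 405.8 CPM in the knockout against 204.3 and 219.6 CPM in the wild-type libraries. In all, 7 genes rose and 1 fell among 13134 tested with edgeR, every one by a log2 fold change of at least 1. Without adjustment, 1112 genes were higher and 1072 lower at p under 0.05, and at an adjusted p under 0.1 edgeR gave 36 higher and 6 lower. Groups did not overlap at 6179 genes (47%), where chance alone gives 33.3%.

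**Figure D1:**
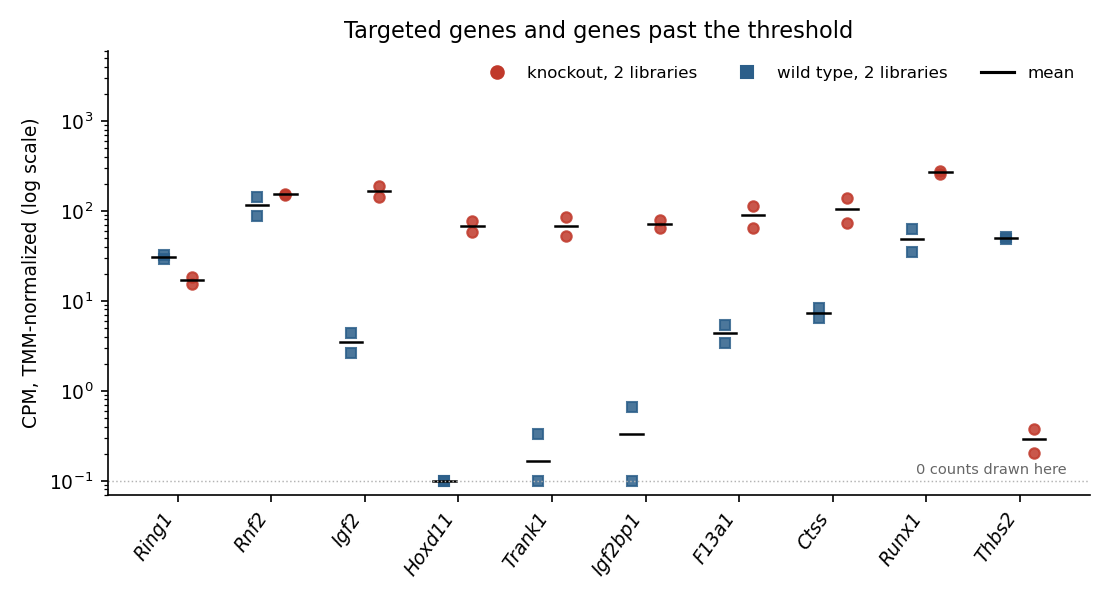
CPM per library on a log axis for the targeted genes Ring1 and Rnf2 and for the 8 genes past the threshold in edgeR, with circles for knockout, squares for wild type, bars for means and 0 counts drawn at a marked line. Igf2 stands at a mean of 164 CPM in the knockout and 3.5 CPM in the wild type, and Thbs2 at 0.288 and 49.6 CPM.

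The number of genes depended on the tool, the low-count filter, single libraries and a trend on gene length and abundance. With no low-count filter edgeR called 802 genes, 455 higher and 347 lower, and with a filter of at least 1 CPM in 2 libraries it called 1. With the trend removed, a setting chosen after the data were seen, it called 1 of the 8 genes, Igf2. Limma-voom called 0 genes (1956 at an unadjusted p under 0.05) where DESeq2 called 1792, 901 higher and 891 lower, against the 8 of edgeR. Without knockout replicate 1 edgeR called 1 gene, without knockout replicate 2 it called 0 (1098 unadjusted), without wild-type replicate 1 it called 32 and without wild-type replicate 2 it called 60. Without wild-type replicate 2, Trank1 and Igf2bp1 stood at 0 wild-type counts, at least 56.8-fold and at least 64.4-fold higher in the knockout, and without wild-type replicate 1 their ratios were 194 (counting interval 34.7 to 7665) and 110 (30.3 to 908). Without knockout replicate 2 the ratio of Thbs2 was 246 (43.8 to 9763), and without knockout replicate 1 it was 133 (45.1 to 650). Bounds against 0 wild-type counts were lower without a wild-type library, since the floor then covers fewer counts: Hoxd11 was at least 70.1-fold higher without replicate 1 and at least 61.6-fold without replicate 2. All 8 genes were among the calls without either wild-type library, and Igf2 was the gene called without knockout replicate 1. In the authors' deposited table, 1066 genes were marked higher and 187 lower in the knockout, among them all 8 genes that edgeR called. Those marks take a log2 fold change of at least 1 in size and reach an adjusted p of 0.0998 in the authors' own test. At an adjusted p under 0.05 that table holds 901 higher and 891 lower genes, the same numbers as DESeq2 here. The log2 fold changes of the authors' deposited table and of edgeR correlated at Pearson 0.996 across 13134 genes, although the counts of genes past a threshold differed. Both come from the same counts, so the shared genes and this correlation are no independent check.

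Developmental transcription factors outside the Hox clusters, which PRC1 is known to hold silent, were the list with the largest median shift with all libraries. With members at 0 set to their bounds, Merkel cell genes had the larger median without wild-type replicate 2 (3.2 against 2.52). Of 180 members in the counts, 67 were expressed enough to test, 33 rose and 0 fell when adjusted over the list alone, 34 did not pass, and 0 passed over all genes tested. In both wild-type libraries 30 of the 180 reached 1 CPM, and in both knockout libraries 83 did. Members near 0 in the wild type could pass the count filter through the knockout libraries alone, and could hardly fall. The 0 that fell and the list's median depend on this. Pax6, a regulator of eye development, rose from 0.524 ± 0.203 to 31 ± 19.5 CPM, a ratio of 52 with a counting interval of 17.7 to 253, and Onecut2, a liver and neural factor, rose 19.4-fold to 38.4 ± 17.7 CPM. Foxf2, a mesenchymal forkhead factor, rose from 0 counts to 21.3 ± 0.15 CPM, at least 40-fold higher (edgeR adjusted p = 0.0107 over the list alone for these 3). Without knockout replicate 1 the ratio of Pax6 was 32.2 (10.8 to 158), and without knockout replicate 2 it was 84.1 (28.4 to 411). The most abundant members did not pass: Bnc2 stood at 252 ± 33.4 against 192 ± 14.6 CPM, and Pou3f1 at 119 ± 10.1 against 114 ± 17 CPM. The list's median log2 fold change was 3.47, or 3.19 with its 14 members at 0 in a genotype set to their bounds. Without wild-type replicate 2, 54 of 97 tested members stood at 0 in a genotype, and the median was 6.41 as fitted and 2.52 with these at their bounds. Without wild-type replicate 1 it was 40 of 97, with medians of 4.38 and 2.21. With the trend on gene length and abundance removed, a setting chosen after the data were seen, the median was 2.35 and 5 members, not 33, passed over the list alone in edgeR. Camera gave the list an adjusted p of 1.74e-18, and an adjusted p = 0.253 with an estimated correlation. The authors' deposited table marked 45 members higher and 0 lower.

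Hox genes, which set position along the body axis, gave 1 member past the threshold over all genes tested and 9 that rose with 0 that fell when adjusted over the list alone, with 24 of 33 not passing. In both wild-type libraries 22 of 39 Hox genes reached 1 CPM, and in both knockout libraries 32 did. Of the 33 tested, 7 stood at 0 counts in the wild type, so they passed the count filter through the knockout libraries alone and could not fall. The 0 that fell depends on this. Beside Hoxd11, Hoxd10 rose from 0 counts to 37.7 ± 4.92 CPM, at least 69.2-fold higher, and Hoxa10 rose 49.4-fold from 1.02 ± 0.911 to 53 ± 21.9 CPM (edgeR adjusted p = 0.00158 over the list alone for each). Hoxd13 rose from 0 counts to 33.2 ± 12.2 CPM, at least 58.4-fold higher, and Hoxd9, Hoxc10, Hoxb13 and Hoxa11 rose from 0 counts by at least 21.7-fold to at least 32.8-fold. Without knockout replicate 2 the bounds were at least 6.82-fold for Hoxa11 (21.7 with all libraries) and at least 16.7-fold for Hoxb13 (29.3). Transcripts of neighbouring Hox genes overlap, and the use of strand in counting is not given in the sources used here, so reads of 1 Hox gene may be counted for its neighbour. Without wild-type replicate 1 the log2 fold change of Hoxa10 was 4.98 in place of 5.63, and without wild-type replicate 2 its ratio was 149 (counting interval 26.7 to 5904). The list's median log2 fold change was 0.64 (1.08 without knockout replicate 1, 1.2 and 1 without wild-type replicates 1 and 2, 0.4 with the trend on gene length and abundance removed), with a camera adjusted p of 1.74e-06 and an adjusted p = 0.253 with an estimated correlation. The authors' deposited table marked 10 Hox genes higher and 0 lower.

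Among PRC1 subunits 0 of 24 passed over all genes tested, and 2 rose with 0 that fell when adjusted over the list alone. Auts2, a component of a variant PRC1 linked to active transcription, rose 2.84-fold from 58.6 ± 0.182 to 167 ± 9.15 CPM, and Bcor, a variant PRC1 corepressor, rose 2.57-fold from 64.3 ± 11.6 to 165 ± 3.45 CPM (edgeR adjusted p = 0.003 and 0.00454 over the list alone). Phc3 stood at 226 ± 21.5 against 200 ± 10.7 CPM. The median log2 fold change was 0.41 (camera adjusted p = 0.00971; adjusted p = 0.458 with an estimated correlation). The camera call ended without knockout replicate 1 (adjusted p = 0.0654) and without knockout replicate 2 (0.077). Of 11 PRC2 subunits, the complex that methylates histone H3 at Polycomb targets, 0 passed over all genes tested and 1 fell when adjusted over the list alone, Rbbp7, a histone-binding chaperone, from 391 ± 63.6 to 233 ± 7.62 CPM. Mtf2 stood at 194 ± 29.1 against 221 ± 16 CPM, and the PRC2 list did not pass (median log2 fold change -0.19, mean 0.11, camera adjusted p = 0.611). The PRC2 median was -0.202 and -0.00298 without knockout replicates 1 and 2, and -0.165 and -0.0289 without wild-type replicates 1 and 2.

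Of 8 cell cycle inhibitors, 0 passed over all genes tested and 2 rose when adjusted over the list alone. Cdkn2a, a classical Polycomb target that encodes p16 and p19, rose from 0 counts to 5.9 ± 0.635 CPM, at least 11.3-fold higher, and the imprinted Cdkn1c rose 9.32-fold from 4.55 ± 5.36 to 43.2 ± 9.47 CPM (edgeR adjusted p = 0.0385 over the list alone for each). The log2 fold change of Cdkn1c, 3.22, was 2.37 without wild-type replicate 1, and without wild-type replicate 2, which leaves 2 wild-type counts, its ratio was 54.8 (counting interval 15.1 to 453). Cdkn1a stood at 150 ± 7.61 against 184 ± 18.3 CPM and Cdkn1b at 110 ± 16.9 against 153 ± 22.7 CPM, and the list as a whole did not pass (camera adjusted p = 0.785). Cdkn1c lies in the same imprinted cluster as Kcnq1ot1, the transcript with the highest count in 3 of 4 libraries, at 1478 ± 200 CPM in the knockout and 1123 ± 306 CPM in the wild type. Kcnq1ot1 is antisense to Kcnq1, so without strand its reads cannot be told from those of Kcnq1.

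Genes that mark follicle stem cells moved in both directions. Of 29 tested, Runx1 passed over all genes tested, and 4 rose and 1 fell when adjusted over the list alone. Krt79, a keratin of the follicle opening and upper follicle, rose 17.1-fold from 11.4 ± 13.4 to 192 ± 42.7 CPM, Nfatc1, a factor of bulge stem cell quiescence, rose 29.6-fold from 1.17 ± 1.65 to 36.4 ± 3.38 CPM, and Sox9, a factor of bulge identity, rose 2.27-fold to 164 ± 11.2 CPM. Wif1, a secreted Wnt inhibitor, fell 8.18-fold from 164 ± 121 to 20.2 ± 6.56 CPM (edgeR adjusted p = 0.00534 over the list alone). Without wild-type replicate 1 the log2 fold changes were 6.57 for Krt79 (4.1 with all libraries), 3.95 for Nfatc1 (4.89) and -1.96 for Wif1 (-3.03), and without wild-type replicate 2 they were 3.18 for Krt79 and -3.66 for Wif1, while Nfatc1 then stood at 0 wild-type counts, at least 31.4-fold higher. Lgr5, the gene used for sorting, stood at 245 ± 7.87 against 167 ± 38.1 CPM, and Lhx2 at 125 ± 18.8 against 124 ± 24.4 CPM. The list did not pass as a whole (median log2 fold change 0.02, camera adjusted p = 0.402). Its median was -0.106 and 0.156 without knockout replicates 1 and 2, and -0.0109 and 0.295 without wild-type replicates 1 and 2.

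Basal keratinocyte genes also moved in both directions. Of 20 basal keratinocyte genes, 0 passed over all genes tested, and 3 rose and 3 fell when adjusted over the list alone. Lama3, a chain of laminin 332 in the basement membrane, rose 4.64-fold from 34.9 ± 20.5 to 161 ± 20.6 CPM, with Thbs1 and Dst, while the desmosomal protein Perp fell from 726 ± 107 to 413 ± 90 CPM, with Cd9 and Sfn. Without wild-type replicate 1 the log2 fold change of Lama3 was 2.99 in place of 2.21. Dsc3 stood at 493 ± 29.7 against 618 ± 13.5 CPM. The basal list had a median log2 fold change of 0.02 while camera pointed down (adjusted p = 0.887). With the trend on gene length and abundance removed, a setting chosen after the data were seen, Sfn turned (log2 fold change 0.0746) and camera called the basal list as higher (adjusted p = 0.019). Of 31 epidermal differentiation genes, 0 passed over all genes tested and 1 fell when adjusted over the list alone, Ly6d, a surface protein of differentiating keratinocytes, from 197 ± 5.68 to 65.6 ± 8.5 CPM. Dsg1a stood at 315 ± 9.03 against 350 ± 6.81 CPM and Zfp750 at 200 ± 10.9 against 269 ± 37.9 CPM, with a list median of 0.08 and a camera direction of down (adjusted p = 0.679). None of 5 stress keratinocyte genes passed either adjustment: Krt17 stood at 328 ± 83.7 against 381 ± 71.1 CPM and Il1rn at 27.3 ± 8.6 against 49.9 ± 15.9 CPM (median log2 fold change -0.21, mean 1.01, camera adjusted p = 0.935). The stress median was -0.45 without knockout replicate 1, 0.01 without knockout replicate 2, 1.54 without wild-type replicate 1 and -0.42 without wild-type replicate 2.

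Genes of the hair lineages, the matrix, inner root sheath and hair shaft, fell as a list. Of 25 tested, 0 passed over all genes tested, and 9 fell and 1 rose when adjusted over the list alone. Krt25 fell 2.23-fold from 455 ± 8.61 to 204 ± 17 CPM and Krt71 fell 2.31-fold from 937 ± 178 to 406 ± 38.6 CPM (edgeR adjusted p = 0.0027 over the list alone for each), and Krt28 fell 2.02-fold to 256 ± 10.7 CPM, all keratins of the inner root sheath. Krt75, a keratin of the companion layer, rose 2.01-fold from 108 ± 21.6 to 217 ± 2.36 CPM, and Cux1 stood at 713 ± 102 against 873 ± 159 CPM. Krt25, Krt27 and Krt28 are related in sequence, as are Krt71 and Krt73, and could share reads within each group, so the split within each group is uncertain. The median log2 fold change was -0.71 (camera adjusted p = 1.86e-06; adjusted p = 0.534 with an estimated correlation), and -0.29 without knockout replicate 2 as well as without wild-type replicate 1, and -0.39 with the trend on gene length and abundance removed. Short abundant transcripts moved down with this list: among 2388 abundant genes the fold change correlated with gene length at Spearman 0.575, across genes, and 76 ribosomal protein genes had a median log2 fold change of -0.82. Of 10 sebocyte genes, 0 passed over all genes tested and 1 fell when adjusted over the list alone, Mgst1, a microsomal glutathione transferase, from 264 ± 31.6 to 153 ± 20 CPM. The lipid synthesis genes Scd1 and Fasn stood at 259 ± 9.39 against 341 ± 45.9 CPM and 277 ± 32.4 against 287 ± 13.4 CPM (list median 0.15, camera direction down, adjusted p = 0.611). The sebocyte median was -0.0297 and -0.296 without knockout replicates 1 and 2, and -0.125 and 0.211 without wild-type replicates 1 and 2.

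**Figure D2:**
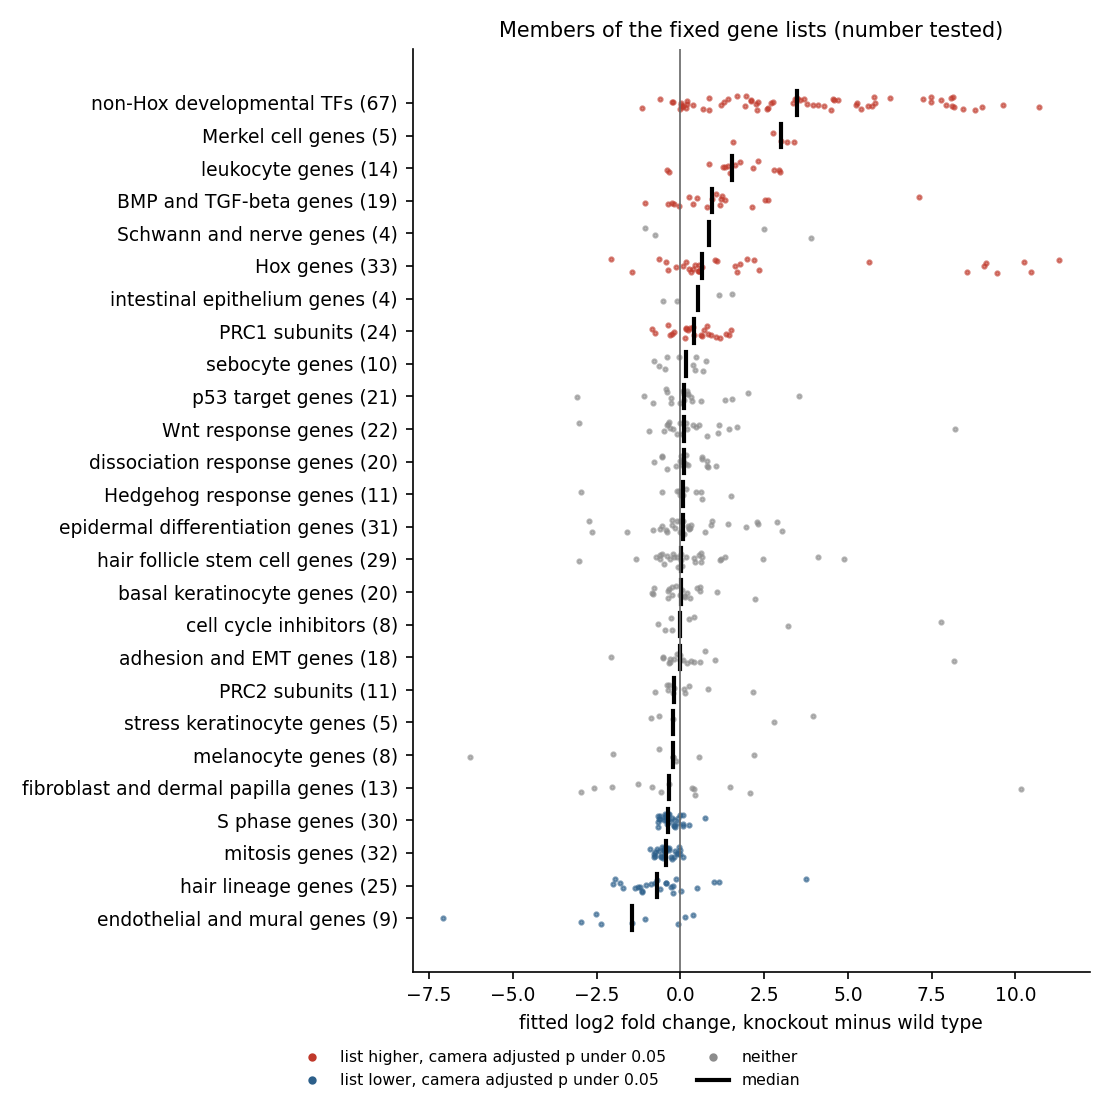
Fitted log2 fold change of knockout over wild type for each tested member of the 26 lists, a dot per gene and a black bar for the list median, with red for lists higher and blue for lists lower by camera at its preset correlation. Medians run from 3.47 for non-Hox developmental transcription factors to -1.45 for endothelial and mural genes, and values of genes at 0 counts in a genotype depend on the fit.

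**Figure D3:**
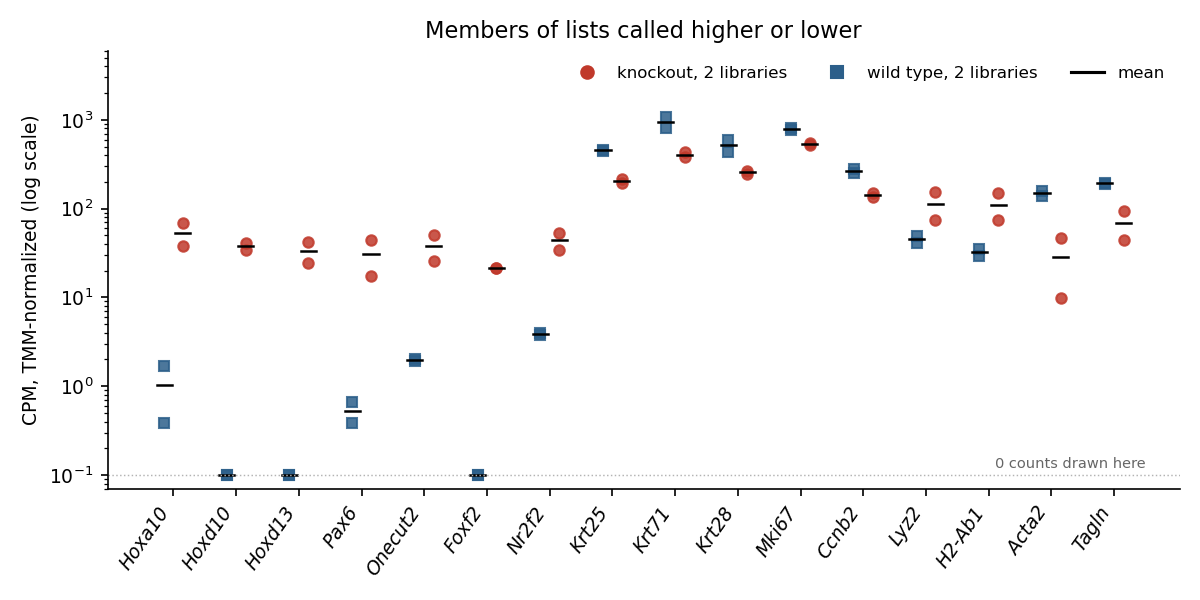
CPM per library on a log axis for members of lists that camera called higher or lower, with circles for knockout, squares for wild type, bars for means and 0 counts drawn at a marked line. Foxf2, Hoxd10 and Hoxd13 stand at 0 counts in both wild-type libraries, and Krt25 at a mean of 204 CPM in the knockout and 455 CPM in the wild type.

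Markers of other skin cells also differed between genotypes. Leukocyte genes rose as a list: of 14 tested, 0 passed over all genes tested and 5 rose with 0 that fell when adjusted over the list alone. H2-Ab1, a chain of the class II antigen-presenting molecule, stood at 148 and 75.2 CPM in the knockout and 29.2 and 35.4 CPM in the wild-type libraries, and rose with Lyz2 (114 ± 56 against 45 ± 6.12 CPM), Cd74, Laptm5 and Fcer1g. In both wild-type libraries 13 of 19 members reached 1 CPM. The median log2 fold change was 1.55 (camera adjusted p = 0.000132; adjusted p = 0.701 with an estimated correlation), and the call ended without knockout replicate 1 (median 0.85, camera adjusted p = 0.23). Without that library the log2 fold changes were 0.72 for Lyz2 (1.34 with all libraries) and 2.13 for Cd74 (2.93), and without wild-type replicates 1 and 2 that of Cd74 was 5.15 and 2.05. Without wild-type replicate 2 that of Laptm5 was 3.67 in place of 2.79. Endothelial and mural genes fell as a list: of 9 tested, 0 passed over all genes tested and 3 fell when adjusted over the list alone. These were the contractile genes Acta2 (28.3 ± 26 against 148 ± 14.2 CPM) and Tagln (69.7 ± 35.4 against 192 ± 3.17 CPM) and the pericyte gene Rgs5, at 0 counts against 3.59 ± 0.83 CPM, at least 15.4-fold lower. In both wild-type libraries 8 of 16 members reached 1 CPM. The endothelial marker list's most abundant member, Cspg4, stood at 158 ± 31 against 120 ± 25.2 CPM. The list's median log2 fold change was -1.45 (camera adjusted p = 0.00971; adjusted p = 0.458 with an estimated correlation), and without wild-type replicate 2 it was 0.27, or 0.02 with its member at 0 set to the bound, with a camera adjusted p of 0.521. Without knockout replicate 1 the median was -2.35 and the log2 fold change of Acta2 -1.66 in place of -2.36, and without knockout replicate 2 that of Acta2 was -3.91 and that of Tagln -2.12 in place of -1.45. Rgs5 was then at least 9.51-fold and at least 5.86-fold lower.

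Merkel cell genes, markers of the touch receptors of the epidermis, rose as a list of 5 tested members, 2 of them when adjusted over the list alone and 0 over all genes tested. Krt18, a simple-epithelium keratin, rose 9.1-fold from 4.38 ± 1.36 to 40.2 ± 1.12 CPM and Ncam1, a neural adhesion molecule, rose 8.06-fold to 21.5 ± 7.54 CPM, while Krt8 stood at 36.4 ± 18.6 against 12.3 ± 10.9 CPM. Of 18 Merkel members, 6 are also in another list and 4 reached 1 CPM in both wild-type libraries. The median log2 fold change was 3.01 (camera adjusted p = 7e-04; adjusted p = 0.534 with an estimated correlation), and the call ended without wild-type replicate 1 (camera adjusted p = 0.0623). With the trend on gene length and abundance removed, a setting chosen after the data were seen, the Merkel median was 1.68. Of 13 fibroblast and dermal papilla genes, 0 passed over all genes tested, and 1 rose and 1 fell when adjusted over the list alone. Crabp1, a retinoic acid binding protein, rose from 0 counts to 31.2 ± 5.01 CPM, at least 56.9-fold higher, and Dcn, the matrix proteoglycan decorin, fell from 512 ± 115 to 215 ± 79.9 CPM. Sparc stood at 80.2 ± 15 against 119 ± 44.2 CPM. The collagen gene Col1a1 stood at 13.3 and 17.8 CPM in the knockout and 14.4 and 113 CPM in the wild-type libraries. In both wild-type libraries 11 of 18 fibroblast members reached 1 CPM. The fibroblast list did not pass (median log2 fold change -0.35, mean 0.33, camera adjusted p = 0.538), but without wild-type replicate 1 it passed as lower (median -0.74, camera adjusted p = 0.0015). Its median was -1.23 without knockout replicate 1, -0.67 without knockout replicate 2, and -0.03 with camera pointing up without wild-type replicate 2.

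The lists of 3 further cell types did not pass. None of 8 melanocyte genes passed either adjustment, with Kit at 102 ± 21 against 118 ± 12.8 CPM and Mitf at 26.7 ± 23.1 against 17.9 ± 3.64 CPM (median log2 fold change -0.22, camera adjusted p = 0.402). The melanocyte median was -0.92 and -0.41 without knockout replicates 1 and 2, and -0.1 and -0.37 without wild-type replicates 1 and 2. None of 4 Schwann and nerve genes passed either adjustment, with Mbp at 11.2 ± 3.23 against 1.95 ± 0.0733 CPM (median 0.87, camera adjusted p = 0.641). The Schwann median was -1.57 without knockout replicate 1, -0.07 without knockout replicate 2, and 2.64, or 1.86 with members at 0 set to their bounds, without wild-type replicate 2. None of 4 intestinal epithelium genes passed either adjustment, with Lgals4 at 14.1 ± 1.05 against 15.2 ± 5.9 CPM and Lyz1 at 16.4 ± 9 against 5.64 ± 0.993 CPM (median 0.52, camera adjusted p = 0.877). The intestinal median was -0.2 without knockout replicate 2, 0.78 without wild-type replicate 1 and 5.8 without wild-type replicate 2, the last pair 0.41 and 1.11 with members at 0 set to their bounds. Lyz1 is closely related to Lyz2 and could share its reads.

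Among signalling genes, the BMP and TGF-beta list rose. Of 19 tested, 0 passed over all genes tested, and 5 rose and 1 fell when adjusted over the list alone. Bmp4, a ligand of the dermal papilla and hair matrix, rose 5.72-fold from 7.92 ± 2.23 to 45.4 ± 4.1 CPM, Tgfb3 rose from 0.167 ± 0.236 to 27.8 ± 17.7 CPM, a ratio of 173 with a counting interval of 30.9 to 6867, and Bmp7, Inhbb and Tgfb2 rose as well. Id3, a direct BMP response gene, fell 2.06-fold from 299 ± 6.92 to 145 ± 27.6 CPM (edgeR adjusted p = 0.00721 over the list alone). The list's most abundant member besides Id3, Fstl1, stood at 251 ± 15.7 against 210 ± 28.7 CPM. The median log2 fold change was 0.96 (camera adjusted p = 0.0241; adjusted p = 0.458 with an estimated correlation), and the call ended without knockout replicate 1 (median 0.43, camera adjusted p = 0.216) and without wild-type replicate 1 (0.0901). With the trend on gene length and abundance removed the median was 0.4. Without wild-type replicate 2, Tgfb3 stood at 0 wild-type counts, at least 27-fold higher, and the log2 fold change of Inhbb was 2.83 in place of 2.14. The ratio of Tgfb3 was 86.4 (15 to 3457) without knockout replicate 2 and 92.3 (16.5 to 3655) without wild-type replicate 1. Of 22 Wnt response genes, 0 passed over all genes tested and Wif1 alone fell when adjusted over the list alone. Cd44 stood at 426 ± 60.3 against 408 ± 55.6 CPM and Ctnnb1, which encodes beta-catenin, at 339 ± 57.7 against 442 ± 4.94 CPM (list median 0.11, camera direction down, adjusted p = 0.935). None of 11 Hedgehog response genes passed either adjustment: Gli1 stood at 196 ± 26.1 against 174 ± 38.6 CPM, Ptch1 at 172 ± 7.81 against 184 ± 20.3 CPM, and the ligand Shh at 6 ± 5.5 against 46.4 ± 8.5 CPM (list median 0.09, mean -0.02, camera direction up, adjusted p = 0.935).

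Cell division genes fell as lists while few single members passed. Of 32 mitosis genes, 0 passed over all genes tested and 6 fell with 0 that rose when adjusted over the list alone. Mki67, the proliferation marker Ki-67, fell 1.48-fold from 790 ± 25 to 534 ± 12.8 CPM and Ccnb2, cyclin B2, fell 1.87-fold from 268 ± 19.1 to 143 ± 11.7 CPM (edgeR adjusted p = 0.0429 and 0.0354 over the list alone), with Cenpa, Ccnb1, Ube2c and Cdca8. Top2a stood at 540 ± 76.4 against 750 ± 61.2 CPM. The mitosis list's median log2 fold change was -0.44, and -0.17 with the trend on gene length and abundance removed (before removal, camera adjusted p = 5.39e-08; adjusted p = 0.253 with an estimated correlation). Of 30 S phase genes, 0 passed either adjustment, with the ribonucleotide reductase subunits Rrm2 at 221 ± 15.8 against 352 ± 55.9 CPM and Rrm1 at 219 ± 11.2 against 348 ± 64.9 CPM. The S phase list had a median log2 fold change of -0.36 (camera adjusted p = 0.000814; adjusted p = 0.728 with an estimated correlation), and of -0.23 without knockout replicate 1, and the call ended without wild-type replicate 1 (median -0.14, camera adjusted p = 0.18) and with the trend on gene length and abundance removed, a setting chosen after the data were seen (0.492). Ribosomal protein genes, at a median log2 fold change of -0.82, and other short abundant transcripts moved down with both lists.

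None of 21 p53 target genes passed either adjustment, with Trp53inp1 at 356 ± 12.6 against 312 ± 65.6 CPM, and Perp at the values above (median log2 fold change 0.11, camera adjusted p = 0.968). Dissociation response genes, which rise while tissue is taken apart, also gave 0 of 20 members under either adjustment: the chaperone genes Hspa8 and Hsp90aa1 stood at 378 ± 54.5 against 646 ± 130 CPM and 354 ± 34.6 against 515 ± 16.3 CPM (median 0.1, camera adjusted p = 0.935). Adhesion and EMT genes gave 0 of 18, with the desmosomal genes Dsp at 632 ± 17.2 against 786 ± 83.1 CPM and Jup at 430 ± 45.3 against 618 ± 115 CPM (median -0.01, mean 0.4, camera adjusted p = 0.785). Over the 26 lists, camera called 6 higher and 4 lower at its preset correlation, and 0 with an estimated correlation. With the trend on gene length and abundance removed, camera also called hair follicle stem cell genes higher (adjusted p = 0.0221), dissociation response genes higher (0.00521) and melanocyte genes lower (0.0165). Leaving out 1 library turned the camera direction of 11 lists, none of them called with all libraries. By fry, whose p asks whether a list moves 1 way on balance without comparing it with other genes, 0 lists passed (smallest adjusted p = 0.0624), while 15 passed its test for change in either direction.

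The peak lists ask where Ring1b, the subunit encoded by Rnf2, binds in 2 Lgr5-positive stem cell types. HFSC had 6754 Ring1b peaks with a median width of 290 bp and ISC 4444 peaks with a median width of 274 bp. Of the HFSC peaks, 1720 (25.5%, Wilson 95% interval 24.4 to 26.5) overlapped an ISC peak by at least 1 bp, and 1729 of the ISC peaks (38.9%, 37.5 to 40.3) overlapped an HFSC peak. Random placements of the peaks gave means of 9.02 and 9.13 overlaps, with highest values of 23 and 19 in 1000 draws, so the observed overlaps were 191 and 189 times those means. These placements were uniform along each chromosome and kept neither the clustering of peaks nor a preference for a kind of site. Lists that merely favour the same kind of region would also exceed them, so the ratios do not measure shared Ring1b binding. The lists shared 490792 bp of 3501238 covered, a Jaccard index of 0.14. Each list came from 1 library, so the shares describe these peak lists and no test between cell types was made, and a peak missing from a list may lie below its calling threshold.

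By the authors' fold over background, the highest HFSC peak lay on chromosome 11 at 21892716 to 21894769 (mm9; fold 34.6), and the next on chromosome 6 at 83019938 to 83021529 (30.7), chromosome 4 at 115610666 to 115612560 (28.2), chromosome 7 at 138698739 to 138701003 (26.5) and chromosome 15 at 102793553 to 102794690 (24.7). The highest ISC peaks lay on chromosome 6 at 83019802 to 83021787 (28.9), chromosome 11 at 21893219 to 21895344 (25.5), chromosome 9 at 55389392 to 55394502 (20.5), chromosome 6 at 49167449 to 49168896 (20) and chromosome 13 at 40824611 to 40826395 (16.6). All 10 overlapped a peak of the other list. Peaks also clustered. The 100-kb windows with most HFSC peaks were chromosome 2 from 74500001 to 74600000, with 31 HFSC and 23 ISC peaks, chromosome 11 from 96100001 to 96200000, with 28 and 25, and chromosome 6 from 52100001 to 52200000, with 26 and 51. These 3 were also among the 4 windows with most ISC peaks, beside chromosome 14 from 122800001 to 122900000, with 13 HFSC and 23 ISC peaks. Windows with at least 5 peaks numbered 192 in HFSC and 104 in ISC, 56 of them in both. Of those HFSC windows 75.5% held an ISC peak, and of those ISC windows 95.2% held an HFSC peak. Over all windows with a peak, 1725 held peaks of both lists, of 3940 with an HFSC peak and 2584 with an ISC peak.

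**Figure D4:**
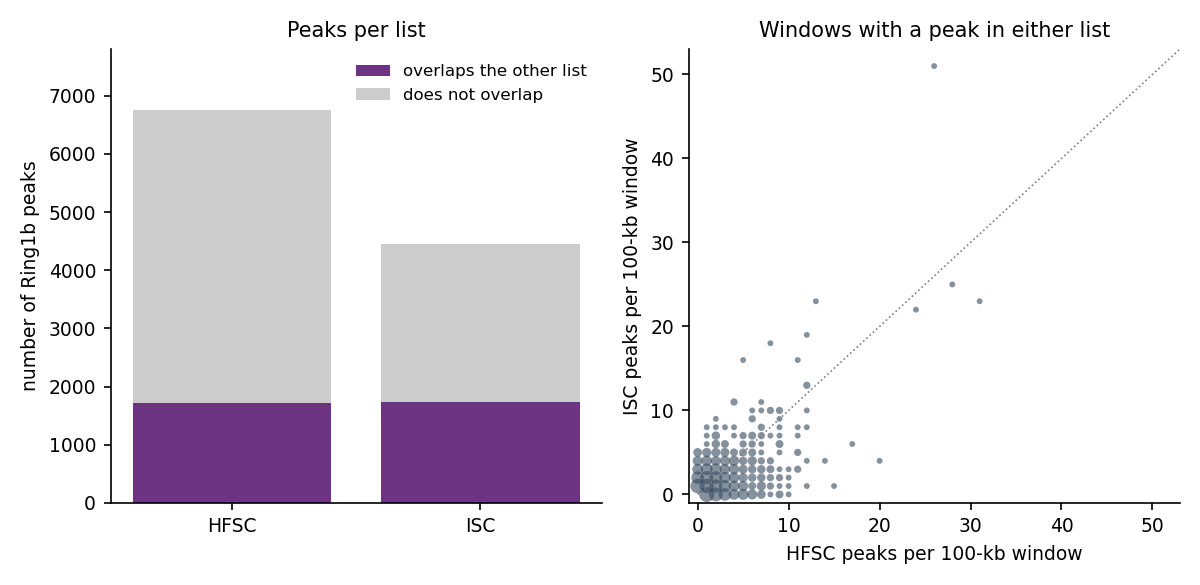
Left, the number of Ring1b peaks per list, split into those that overlap the other list by at least 1 bp (1720 of 6754 in HFSC, 1729 of 4444 in ISC) and those that do not. Right, ISC against HFSC peaks per 100-kb window that holds a peak of either list, with dot size growing with the number of windows and a dotted line of equal counts; the window on chromosome 6 with 26 HFSC and 51 ISC peaks stands furthest above it.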

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

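Of the alternatives given in this part, those chosen only after the result was seen were thinning, removal of the length and abundance trend, and the crossed block. The planned comparison of promoter peaks with expression and its alternatives (other promoter windows, matched background genes, a block) were not run, since no mm9 annotation was used here. With 1 library left in a genotype, the lone library is assumed to vary like the other genotype. With 2 libraries per genotype and at most 7740945 counts, edgeR's test recovered 24% of 50 simulated genes changed 2-fold. These genes had a mean above 5 CPM, and recovery at lower counts was not tried. Where no cause is named, the cause was not tested.

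Counts of genes past the adjusted threshold, 8 in edgeR's test, were the same with RLE factors (8), within 1.5 times with library size alone and after thinning (10 each), 802 with no low-count filter (455 higher, 347 lower), 1 with a filter of 1 CPM in 2 libraries, 1 at an adjusted p under 0.01, 1 with the trend removed (1292 unadjusted), 1792 in DESeq2 (14502 genes), 964 higher and 924 lower in DESeq2 on the 13134 genes of edgeR's test, 716 in DESeq2 on these 13134 with the trend removed, and 0 in limma-voom (1956 unadjusted). Leaving out a library gave 0 to 60. The median log2 fold change of all genes was 0.034, and 0.13 with library size alone. The 8 genes passed in 8 of 13 alternatives each (Igf2 in 11), with highest adjusted p values of 0.154 to 0.211 across edgeR, DESeq2 and limma-voom. Of 160 named genes, all 160 kept direction and side of the threshold with RLE factors, and 105 that did not pass in edgeR's test passed in DESeq2.

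Replicate numbers are not said to mark a shared animal or day, and same-numbered libraries deviated apart (correlation -0.14). With the replicate block, edgeR called 416 genes (213 higher, 203 lower); the p53 target list then pointed down (camera adjusted p = 0.9), and no list gained or lost a call. The crossed pairing gave 8 genes, 7 of them shared with the fit without a block.

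Lists called by camera went from 10 to 0 with an estimated correlation and to 0 by fry. Estimated-correlation and fry adjusted p values were 0.458 and 0.1 for PRC1 subunits, 0.253 and 0.0624 each for Hox genes, non-Hox developmental TFs and mitosis genes, 0.534 and 0.304 for hair lineage genes, 0.534 and 0.205 for Merkel cell genes, 0.701 and 0.403 for leukocyte genes, 0.458 and 0.27 for endothelial and mural genes, 0.458 and 0.176 for BMP and TGF-beta genes, and 0.728 and 0.427 for S phase genes. By fry, Wnt response genes pointed up (0.918). With the trend removed, camera lost S phase genes (0.492) and gained hair follicle stem cell genes (0.0221, up), melanocyte genes (0.0165, down) and dissociation response genes (0.00521, up). It turned basal keratinocyte genes up and past the threshold (0.019), and turned, without a call, the direction of stress keratinocyte, Schwann and nerve, intestinal epithelium and Wnt response genes (0.784 each) and adhesion and EMT genes (0.518). RLE factors, library size alone and thinning changed no list's call or direction.

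Leaving out a library gave camera adjusted p values of 0.0143 to 0.077 for PRC1 subunits, 0.438 to 0.893 for cell cycle inhibitors, 0.696 to 0.909 for basal keratinocyte genes, 0.193 to 0.944 for epidermal differentiation genes, 0.501 to 0.893 for stress keratinocyte genes, 0.000408 to 0.0623 for Merkel cell genes, 0.0015 to 0.875 for fibroblast and dermal papilla genes, 3.94e-10 to 0.23 for leukocyte genes, 7.17e-06 to 0.521 for endothelial and mural genes, 0.749 to 0.893 for Schwann and nerve genes, 0.37 to 0.893 for intestinal epithelium genes, 0.438 to 0.909 for Wnt response genes, 0.703 to 0.902 for Hedgehog response genes, 0.00662 to 0.216 for BMP and TGF-beta genes, 6.57e-07 to 0.18 for S phase genes, 0.696 to 0.909 for p53 target genes and 0.521 to 0.957 for dissociation response genes. The camera direction turned to up without knockout replicate 1 for epidermal differentiation genes, without knockout replicate 2 for stress keratinocyte and Wnt response genes, without wild-type replicate 1 for basal keratinocyte, stress keratinocyte and Wnt response genes, and without wild-type replicate 2 for fibroblast and dermal papilla genes. It turned to down without knockout replicate 1 for Schwann and nerve, Hedgehog response and p53 target genes, without knockout replicate 2 for dissociation response genes, without wild-type replicate 1 for cell cycle inhibitors, intestinal epithelium and dissociation response genes, and without wild-type replicate 2 for p53 target genes. The calls of Hox genes, non-Hox developmental TFs, hair lineage genes and mitosis genes stayed past the threshold without any 1 library, with the trend removed and after thinning.

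Among named genes, none of the 8 past the threshold changed direction. Log2 fold changes that turned with the trend removed were 0.099 for Cdkn1a, 0.0581 for Dsc3, 0.0746 for Sfn, 0.196 for Dsg1a, 0.0832 for Zfp750, 0.485 for Krt17, 0.0746 for Dlx3, 0.116 for Scd1, 0.359 for Fasn, -0.257 for Mitf, 0.0312 for Ctnnb1, 0.112 for Ccnd1, 0.0744 for Hspa8, 0.203 for Hsp90aa1, 0.0847 for Dsp, -0.142 for H19, 0.447 for Krt5, 0.26 for Krt14 and 0.209 for Krt15. With library size alone Fasn (0.0454) and Ptch1 (0.00905) turned, and in limma-voom Mitf (-0.0155) and Lhx2 (-0.0134). Leaving out a library turned Pou3f1 (-0.0712 to 0.211), Krt17 (-0.501 to 0.00903), Fasn (-0.18 to 0.0443), Mitf (-0.794 to 1.24), Lgals4 (-0.453 to 0.335), Cd44 (-0.0941 to 0.209), Gli1 (-0.0381 to 0.395), Ptch1 (-0.221 to 0.0286), Trp53inp1 (-0.0272 to 0.429), Col1a1 (-2.85 to 0.0937), H19 (-1.28 to 3.16) and Lhx2 (-0.167 to 0.214).

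The share of overlapping peaks, 25.5% of HFSC and 38.9% of ISC peaks, moved to 19.3% of HFSC peaks with a −log10 q of at least 5 (39.3% of ISC), 21.2 and 36.6% with a fold of at least 5, 17.2 and 28.0% with an overlap of 50% of the peak, 34.1 and 51.9% within 1000 bp, 28.6 and 29.7% with the 4444 top peaks of each list, and 23.6 and 24.1% with the 2222 top peaks.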

Other observations

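The tests of ribosomal protein, leukocyte, fibroblast and imprinted genes, thinning, and the removal of the length and abundance trend were chosen only after the result was seen, as were the genes named here. Bootstrap intervals (2000 draws) are of the median over the genes of a set. They do not measure the spread between libraries, and they are too narrow where members move together.

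Beside Igf2bp1, both related RNA-binding proteins were more abundant in the knockout, Igf2bp2 at 37.9 ± 1.98 against 3.52 ± 0.684 CPM and Igf2bp3 at 118 ± 37.7 against 38.2 ± 7.82 CPM (n = 2 each, edgeR adjusted p = 0.147 for each, not past the threshold). The imprinted genes Dlk1, a Notch-related fetal ligand, and Peg10, a retrotransposon-derived placental gene, stood at 67.1 ± 9.56 against 0.759 ± 1.07 CPM and 18.6 ± 2.36 against 0.167 ± 0.236 CPM. The Peg10 ratio of 107 has a counting interval of 19 to 4247. Without wild-type replicate 1, Dlk1 was at least 65.5-fold higher and the ratio of Peg10 was 57 (10.1 to 2260), and without wild-type replicate 2 the log2 fold change of Dlk1 was 5.42 and Peg10 was at least 16.7-fold higher. H19, the maternal partner of Igf2, did not follow a genotype, at 50.7 and 12.3 CPM in the knockout and 3.42 and 56.4 CPM in the wild-type libraries.

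A candidate explanation for Igf2, Dlk1 and Cdkn1c is a change of imprinted genes as a class: 28 other tested imprinted genes had a median log2 fold change of 0.61 (95% bootstrap interval 0.18 to 1.34; camera p = 0.00185, or p = 0.0725 with an estimated correlation; with the trend removed the median was 0.0851 and camera p = 0.00687). Of these 28, 5 were higher and 0 lower at an unadjusted p under 0.05 in edgeR, beside 1112 higher and 1072 lower among all 13134 genes tested. The parental allele was not examined.

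Developmental transcription factors higher in the knockout were weighed against total counts, the length and abundance trend, and fibroblast RNA, since many of them are known from dermal cells. After thinning to equal total counts, 84.8% of the members that rose over the list alone (28 of 33) still passed, which argues against the total count, while library complexity was not matched. With the trend removed the median log2 fold change was 2.35 (95% bootstrap interval 1.47 to 3.44, camera adjusted p = 1.42e-14 at its preset correlation). Before removal, camera with an estimated correlation gave an adjusted p of 0.253. With the trend removed 5 members, not 33, passed over the list alone in edgeR's test, for a reason that was not tested. The removal was incomplete, since ribosomal protein genes kept a median of -0.305. What remained therefore cannot decide whether the trend is the whole cause. Fibroblast RNA as the whole cause would raise fibroblast genes about as much as the factors, whose median of 3.47 (2.28 to 4.49) depends on the count filter. The fibroblast median was -0.35 (95% bootstrap interval -1.25 to 0.423) with 12 of 13 below 2.28. The wild-type libraries themselves differed in this list by a median log2 ratio of 1.48. Without wild-type replicate 2 the fibroblast median was -0.03 with camera pointing up, and it stayed below 0 without any other library. No rise of the list's median was thus seen, which argues against fibroblast RNA as the whole cause. The size of the gap is uncertain, and Crabp1 was higher. The trend and fibroblast RNA as a part of the cause stay open. So do RNA of other cell types and a change within the stem cells with the genotype, and the last was not tested.

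Hair lineage, mitosis and S phase genes lower in the knockout were weighed against a technical trend in which short, abundant transcripts lose counts. With the trend removed, hair lineage genes kept a median log2 fold change of -0.39 (95% bootstrap interval -0.779 to -0.0684; camera adjusted p = 0.00521) and mitosis genes of -0.17 (-0.261 to -0.0504; 0.0142). Their medians before were -0.71 and -0.44, with adjusted p = 0.534 and 0.253 by camera with an estimated correlation. Ribosomal protein genes, which mark the trend, also kept -0.305 (-0.344 to -0.269), so the removal was incomplete. What remained in the hair lineage and mitosis genes therefore cannot decide whether the trend is the whole cause. S phase genes went to -0.0615 (-0.205 to 0.00196; camera adjusted p = 0.492), as the trend predicts. On the 13134 genes of edgeR's test, where DESeq2 called 964 higher and 924 lower, it kept 22.3% of these lower calls (206) and 34.8% of these higher calls (335) with the trend removed, and ribosomal protein genes among them went from 66 to 1; within the knockout these genes were also lower in the deeper library, with a median log2 ratio of -0.49 (-0.51 to -0.47) between replicates of 1 genotype. The lower calls of ribosomal protein genes in DESeq2 may thus be technical in part (median log2 fold change -0.82 before and -0.30 after removal of the trend), while fewer hair-forming and dividing cells among those sorted stays open as an untested biological explanation.

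Leukocyte genes higher in the knockout were weighed as RNA of admixed immune cells against a change within the stem cells. Their median log2 ratio of knockout replicate 2 over replicate 1 was -1.01 (95% bootstrap interval -2.77 to -0.75), so the members also moved together within a genotype, which is consistent with a differing share of leukocyte RNA per library. F13a1 and Ctss followed with log2 ratios of -0.79 and -0.89 between the same libraries. Their log2 fold changes of knockout over wild type were larger than the leukocyte list's median of 1.55, at 3.88 and 3.3 or more with any 1 library left out. F13a1 and Ctss were named because they passed the threshold, so changes above the median of a whole list were likely in advance. Their size therefore cannot decide between these explanations. The calls of F13a1 and Ctss may reflect immune cells in the sort or in the skin of knockout animals, and a response of the stem cells was not tested.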
